A study of Mus musculus with 6 samples.

How the data were processed

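The series holds 6 hippocampal RNA sequencing libraries, 3 from floxed mice given AAV2/9-Syn-cre and 3 from floxed mice given a vehicle virus. Per the labels' protocols, RNA with an integrity number above 7 was poly(A) selected, made into strand-marked libraries by the dUTP method and sequenced as 150-base read pairs. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, and the build GRCm39. They give no settings, and the annotation release and the strand setting of the counting are not given in the sources used here.

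A table of 33385 genes was deposited, with an estimated count and an FPKM value for each gene and library, per the file headers. The deposited estimated counts were already whole numbers, so rounding them changed no value. They pile up at 4 and 8: in control replicate 2, for example, 1140 genes had a count of 4, against 576 at 3 and 390 at 5. A read pair may thus add more than 1 to a count, which no table here tests, so the number of counted read pairs is not known. For this reason the counts were also tested after division by 4. The authors' FPKM values are scaled by gene length and library. Within a gene, the ratio of count to FPKM was the same in all libraries up to 1 factor per library, with a median SD of 0.00044 on the log2 scale over 12418 genes, so the pair of units holds a single measurement. Every gene in the table had a count above 0 in at least 1 library. The reference annotation supplied for this work is of another build, so only its gene names were used.

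Libraries were matched to groups by their names in the labels. No pair of libraries matched within sampling noise, since the lowest chi-square per gene between a pair was 30.4. Where the labels do not say that each library is a separate animal, p-values measure the spread between these libraries.

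The comparison used edgeR 4.0.16 in R 4.3.3 on the counts, with filterByExpr (20946 genes kept), TMM factors (0.9895 to 1.017), quasi-likelihood dispersion and F test, and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 28.6%. Standard errors were taken from the fold change and the F statistic, and intervals are at 95%. Single genes of the study's question also had an exact two-sided permutation test of mean log2(FPKM + 1) over the 20 assignments of 3 and 3 libraries. Positive log2 fold changes mean a higher level in the knockdown group.

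Before the data were examined, 42 lists of 690 genes were written from textbook knowledge, of which 686 were found in the table. They cover the PRP19 complex and splicing, BDNF and TrkB signalling, neurogenesis, hippocampal and glial cell types, neighbouring tissues, stress, immunity and metabolism. Each list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 42 lists. Correlations estimated for each list and fry's directional test were run beside it. The rule for named genes took Bcas2, Bdnf, Ntrk2 and Dcx, then up to 10 rises and 10 falls among genes past the threshold whose groups do not overlap and whose mean is at least 1 FPKM, leaving out predicted genes, and then up to 4 members of each list past the threshold, or, where none passed, the 2 with the smallest p as values only. Other genes are said to have been chosen after their values were seen.

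The pipeline was tested on simulated counts for the 20946 genes with the means, library sizes and dispersions of this comparison, 200 genes changed in each of 5 runs. It recovered 10.0% of 1.5-fold changes, 46.8% of 2-fold changes, 63.6% of 4-fold changes and 76.0% of 8-fold changes. Of 537 calls, 46 were of unchanged genes, and 5 runs with no changed gene gave 0 calls and 0 called lists in 210 list tests. The simulated genes vary independently, so the runs do not test how correlated members affect a list.

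Alternatives fixed in advance were RLE factors, no count filter, a replicate block, DESeq2 1.42.0, leaving out each library, other thresholds, and limma on log2(FPKM + 1) for genes with a mean of at least 0.5 FPKM. The limma fit was varied by TPM scaling, median centring, quantile normalization, pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 FPKM, a replicate block, arrayWeights, no trend and a robust trend. Alternatives added after seeing the data were counts divided by 4, a sex term and the 4 libraries without Y-linked counts. Robust dispersions and a mean of at least 5 FPKM in edgeR were added too. GO and KEGG terms given in the table, with 15 to 500 tested genes, were tested with camera as an exploration.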

Results

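RNA sequencing measured gene expression in the hippocampus of mice with a floxed Bcas2 gene, that is, a gene flanked by sites that the Cre recombinase cuts. BCAS2 is a subunit of the PRP19 complex, which activates the spliceosome. The knockdown group (n = 3) had received an adeno-associated virus that carries Cre under the synapsin promoter (AAV2/9-Syn-cre), which is active in neurons, and the control group (n = 3) a vehicle virus. The series title names adult hippocampal neurogenesis, cognitive deficits in Alzheimer's disease and BDNF/TrkB signalling, so the comparison asks which hippocampal transcripts differ once neurons carry Cre. The labels number the mice within each group, give no sex, age or batch, and do not say whether a library comes from 1 animal. Each library held 55914768 to 76481458 deposited counts and 26028 to 26973 genes with a count above 0.

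Bcas2 itself was slightly lower in the knockdown libraries. Its level was 9.04 ± 0.151 FPKM (SD, n = 3) after Cre and 9.68 ± 0.216 FPKM (SD, n = 3) in the controls, which is 93.4% of the control level. The highest knockdown library lay below the lowest control library, and the exact two-sided permutation test gave p = 0.10, the smallest value that 3 against 3 libraries allow. In edgeR's fit over all genes the log2 fold change was -0.07 (95% interval -0.23 to 0.08, adjusted p = 0.861), and the interval spans 85.5% to 106% of the control level. Bcas2 (ENSMUSG00000005687) lies on chromosome 3 from 103078971 to 103086468 on the plus strand of GRCm39. The value sums all exons of the gene over all cells of the tissue, the sources used here do not say which exons are floxed, and cells without synapsin promoter activity keep an intact gene.

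The other genes of the study's question differed by less than the test could call. Bdnf, the neurotrophin that binds TrkB, was at 3.28 ± 0.593 FPKM against 4.51 ± 0.509 FPKM (SD, n = 3 each), a log2 fold change of -0.43 (SE 0.155, adjusted p = 0.792). Its groups did not overlap, with an exact permutation p of 0.10. The Bdnf interval, from -0.79 to -0.07 on the log2 scale, leaves out 0, with an unadjusted edgeR p of 0.0259. Over 25 alternatives the Bdnf value was -0.56 to -0.3 and never passed the adjusted threshold. Ntrk2, which encodes TrkB, was at 26.8 ± 0.688 FPKM against 25.6 ± 2.43 FPKM, a log2 fold change of 0.09 (SE 0.0823, adjusted p = 0.866; exact permutation p = 0.50). Dcx, a marker of newborn neurons, was at 1.72 ± 0.948 FPKM against 2.41 ± 0.678 FPKM, a log2 fold change of -0.46 (SE 0.419, adjusted p = 0.866; exact permutation p = 0.40). It rested on single libraries, at -0.89 without knockdown replicate 1, -0.10 without knockdown replicate 3 and -0.21 without control replicate 2. The Dcx interval, from -1.44 to 0.52 on the log2 scale, leaves room for a fall to 36.8% or a rise to 143% of the control level.

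**Figure D1:**
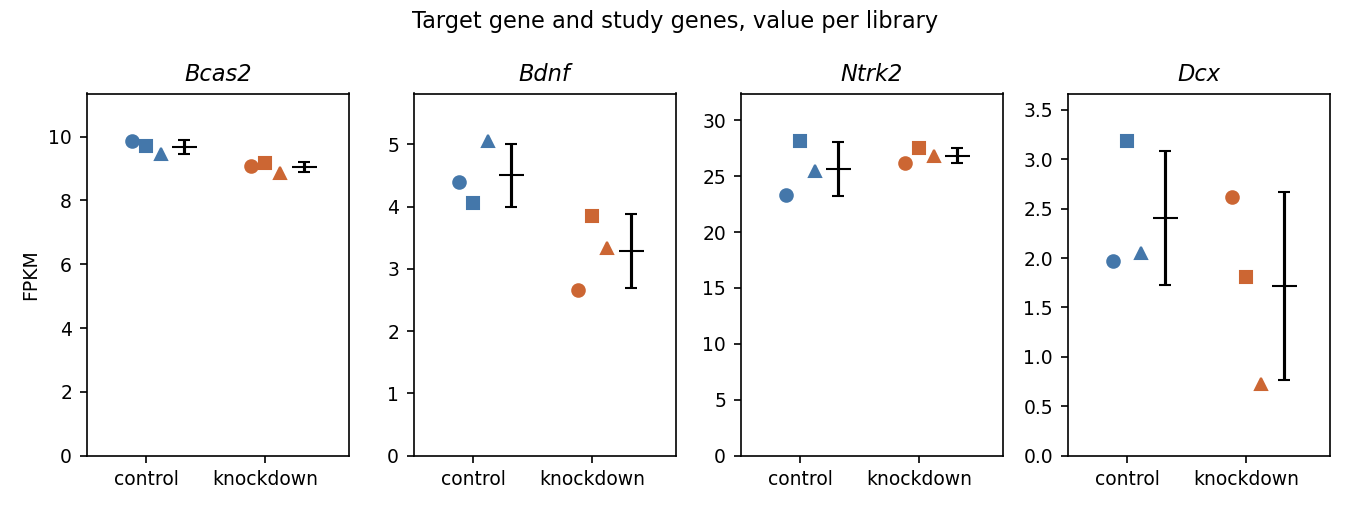
FPKM of Bcas2, Bdnf, Ntrk2 and Dcx in each of the 3 control libraries (blue) and 3 knockdown libraries (orange), with circles, squares and triangles for replicates 1, 2 and 3; the black dash and bar give the mean and SD of each group, and all axes start at 0. Bcas2 sits at 9.04 against 9.68 FPKM and Bdnf at 3.28 against 4.51 FPKM without overlap between the groups, while the values of Ntrk2 and Dcx overlap.

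Across all genes, edgeR's quasi-likelihood test called none of 20946 tested genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it found 1296 genes, 635 higher and 661 lower after Cre, where 1047 are expected with no effect. The same count was 343 to 1603 in the 9 other splits of the 6 libraries into 3 and 3, and 1048 with a replicate block. The smallest adjusted p, 0.0552, belonged to Itih3, a heavy chain of the inter-alpha-trypsin inhibitor family that binds hyaluronan. Itih3 was at 11.1 ± 0.0986 FPKM against 5.93 ± 0.145 FPKM (SD, n = 3 each), a log2 fold change of 0.92 (SE 0.0717), and it passed under 7 of 27 alternatives. DESeq2, given the same genes, called 74, with 26 higher and 48 lower, and left 5725 genes without an adjusted p. The groups did not overlap for any of the 74, and all 74 had an unadjusted edgeR p under 0.05. The 74 were chosen by a test on the same counts, so neither is separate evidence. DESeq2 called 6 to 210 genes in the 9 other splits. Groups did not overlap for 13% of all tested genes, where chance gives 10%. Among the 74, chosen here after their values were seen, were Psmc3ip, a cofactor of meiotic recombination (log2 fold change 1.92), Htr3a, a subunit of the serotonin 5-HT3 receptor (1.02), Tmem59l (0.49) and Ddr1, a collagen receptor (-0.55). Members of the fixed lists among them included the myelin genes Cnp and Cldn11, the oligodendrocyte lineage gene Enpp6, the astrocyte genes Gfap and Fgfr3, the immediate early gene Arc, the immature neuron gene Sox11, the CA1 gene Fibcd1, and Cd9. No gene met the rule for the largest rises and falls, since it needs an adjusted edgeR p under 0.05.

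The groups also differed in sex-linked transcripts, genes looked at here after the values were seen. Xist, the RNA that coats the inactive X chromosome of females, was at 46.8 to 58.6 FPKM in the knockdown libraries and at 43.9 FPKM in control replicate 1. It was at 0.00137 FPKM in control replicate 2 and 0.0213 FPKM in control replicate 3. These last libraries alone had counts for the Y-linked genes Ddx3y (9.56 and 10.8 FPKM), Eif2s3y, Kdm5d and Uty, which were at a count of 0 in the other 4 libraries. Control replicate 3 also stood apart in choroid plexus transcripts. Ttr, the transthyretin gene of that tissue, was at 4180 FPKM there and at 0.349 to 12.9 FPKM elsewhere, and Enpp2 was at 575 FPKM against 16.2 to 37.7 FPKM. On the first principal component, which held 26.5% of the variance, control replicate 3 was at 80.92 and the other libraries lay between -35.06 and 13.46.

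**Figure D2:**
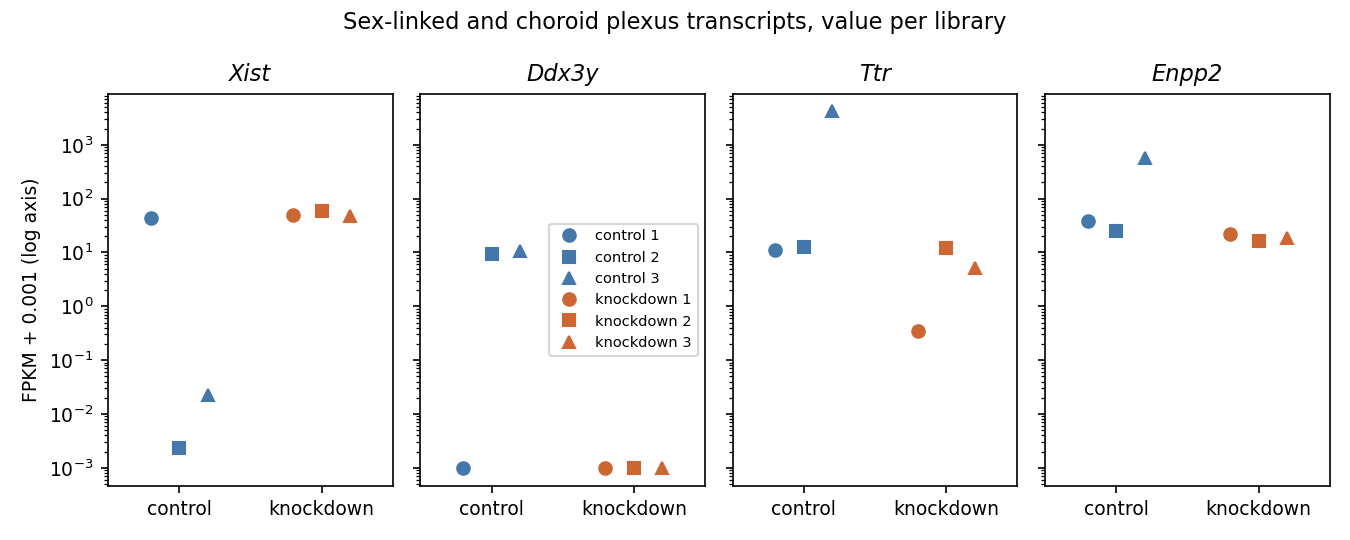
FPKM of Xist, Ddx3y, Ttr and Enpp2 in each library, with 0.001 added to each value so that values of 0 can be drawn on the log axis; blue marks control and orange knockdown libraries, and the symbol gives the replicate. Control replicates 2 and 3 hold Ddx3y and almost no Xist, and control replicate 3 reaches 4180 FPKM of Ttr.

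Of 42 gene lists tested with camera at its preset inter-gene correlation of 0.01, 13 passed an adjusted p under 0.05, 10 lower and 3 higher after Cre. None passed with a correlation estimated for each list, where the smallest adjusted p was 0.71, and none in fry's directional test, where it was 0.14. The estimated form differs in more than the correlation, since its degrees of freedom come from the 6 libraries and not from the genes. For radial glia-like stem cell genes the estimate was -0.01, below the preset, yet the unadjusted camera p went from 0.00843 to 0.048. How often the estimated form finds a real change was not tested, so falling short of it does not show that a list is unchanged. Over the 42 lists, 20 genes passed when adjusted over the list alone and 0 when adjusted over all genes tested. In each list described here the named members are those with the smallest p, given as values.

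Myelin transcripts were lower after Cre. All 16 measured genes of the oligodendrocyte and myelin list were lower, by a mean log2 fold change of -0.58 (SD 0.29 over genes, camera adjusted p = 4.39e-07). With an estimated correlation the adjusted p was 0.75. Adjusted over the list alone, 7 of the 16 passed. Cldn11, a tight junction protein of myelin, had a log2 fold change of -0.63 (SE 0.147), and Cnp, the myelin phosphodiesterase, of -0.67 (SE 0.157), both with an adjusted p of 0.792 in edgeR. The list score was -0.53 to -0.15 in the knockdown libraries, 0.07 and 0.08 in control replicates 3 and 2, and 0.70 in control replicate 1. Without control replicate 1 the mean was -0.34 (camera adjusted p = 6.99e-05).

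Activity-dependent immediate early genes were lower as well. All 20 had a negative log2 fold change, with a mean of -0.49 (camera adjusted p = 8.90e-06; adjusted p = 0.75 with an estimated correlation), and 0 passed when adjusted over the list alone. Arc, which regulates AMPA receptor traffic, had a log2 fold change of -0.97 (SE 0.249) and the nuclear receptor gene Nr4a3 of -0.41 (SE 0.121), each with an edgeR adjusted p of 0.792. The scores overlapped, since control replicate 1 (-0.25) lay below knockdown replicate 1 (0.09). Control replicates 2 and 3, the libraries with Y-linked counts, had the highest scores, 0.67 and 0.25. In the 4 libraries without Y-linked counts, a subset chosen after seeing the data, the mean was 0.06. Control replicate 1 is the only control among them. Without control replicate 2 the mean was -0.23 (camera adjusted p = 0.0357).

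The lists for stages of adult neurogenesis were lower by smaller amounts. The list of neuroblasts and immature neurons had 14 of 17 genes lower and a mean of -0.32 (camera adjusted p = 0.00622; 0.71 is the adjusted p with an estimated correlation). Its members Sox11 and Igfbpl1 had log2 fold changes of -0.46 (SE 0.110) and -1.33 (SE 0.377). The proliferation list had 17 of 19 lower and a mean of -0.46 (adjusted p = 5.17e-04, and 0.71 with an estimated correlation). It was led by Rrm2, a ribonucleotide reductase subunit (-1.05, SE 0.478), and the kinetochore gene Cenpf (-0.80, SE 0.371). Both were at low levels, Rrm2 at 0.303 against 0.641 FPKM with overlapping groups and Cenpf at 0.048 against 0.0847 FPKM. Radial glia-like stem cell genes had 12 of 16 lower and a mean of -0.21 (adjusted p = 0.0272; adjusted p = 0.71 with an estimated correlation). Its leading members went opposite ways, Lpar1 at -0.74 (SE 0.227) and Aldoc, which astrocytes also express, at 0.27 (SE 0.0930). Replication-dependent histones, fixed as a list of technical markers because most of these transcripts lack the poly(A) tail on which the libraries were selected, were lower for all 9 measured genes, with a mean of -0.74 (adjusted p = 3.99e-04; adjusted p = 0.75 with an estimated correlation), among them H2bc4 (-0.74, SE 0.236) and H4c9 (-0.89, SE 0.284). No gene of these 4 lists passed when adjusted over the list alone. Without control replicate 2 the neuroblast (mean -0.27, adjusted p = 0.156), proliferation (-0.35, 0.0757) and stem cell (-0.23, 0.0757) lists no longer passed. Over all alternatives, the proliferation list fell short in 11 of 24, with a mean as near 0 as -0.08, the stem cell list in 10 of 26 and the neuroblast list in 3 of 26. These alternatives include limma differences of log2(FPKM + 1), a scale that pulls genes at low FPKM towards 0. The stem cell list was also lost without knockdown replicate 2 (adjusted p = 0.0693), control replicate 1 (0.123) or control replicate 3 (0.0710), the histone mean was -0.40 without control replicate 3, and the proliferation mean was -0.78 without knockdown replicate 1.

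The mitochondrially encoded genes, fixed as a list of technical markers, were higher, and the genes of sterol synthesis were lower. All 13 mitochondrial genes were higher, by a mean log2 fold change of 0.19 (SD 0.06 over genes, camera adjusted p = 7.68e-07; adjusted p = 0.71 with an estimated correlation). The complex I genes mt-Nd5 and mt-Nd1 had log2 fold changes of 0.33 (SE 0.0849) and 0.20 (SE 0.0672), and after quantile normalization in limma mt-Nd1 was at -0.02 and the list no longer passed (mean 0.06, adjusted p = 0.257). That normalization gives equal values to equal ranks, so it can remove a difference shared by the most abundant genes. mt-Nd1 was at 5050 FPKM in the knockdown group and 4460 FPKM in the controls. Mitochondrial genes took 5.96% to 6.18% of the counts in the knockdown libraries and 5.19% to 5.54% in the controls. Of the nuclear genes of the respiratory chain, 12 of 18 were higher, with a mean of 0.05 (adjusted p = 0.101). Cholesterol synthesis genes were lower for 16 of 18, with a mean of -0.20 (adjusted p = 3.99e-04; adjusted p = 0.75 with an estimated correlation). Cyp51, lanosterol demethylase, had a log2 fold change of -0.40 (SE 0.111) and Idi1, isopentenyl diphosphate isomerase, of -0.41 (SE 0.117). Neither list had a gene past the threshold when adjusted over the list alone. The sterol mean was -0.31 without knockdown replicate 1 and -0.13 without knockdown replicate 2.

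The interferon and complement lists were higher on average and uneven between libraries. Interferon-stimulated genes were higher for 20 of 24, with a mean of 0.76 (adjusted p = 4.71e-04; adjusted p = 0.75 with an estimated correlation), led by Irf7 (1.88, SE 0.519) and the antiviral GTPase Mx1 (3.06, SE 0.978). Mx1 lay near the floor, at 0.123 against 0.0143 FPKM, and its log2 fold change was 0.15 to 7.90 over the alternatives. That range includes limma differences of log2(FPKM + 1), which are pulled towards 0 for genes this low. Complement and MHC class I genes were higher for 14 of 17, with a mean of 0.39 (adjusted p = 0.00542; adjusted p = 0.75 with an estimated correlation), led by H2-K1 (0.86, SE 0.227) and C1qa (0.65, SE 0.221). No gene of either list passed when adjusted over the list alone. The interferon score was 1.00 in knockdown replicate 1 and -0.15 in knockdown replicate 3, against 0.43 in control replicate 3. The interferon list was lost without knockdown replicate 1 (mean 0.39, adjusted p = 0.0982) and without control replicate 2 (0.54, adjusted p = 0.0842), and its mean was 1.55 without control replicate 3. The complement list was lost without knockdown replicate 2 (0.13, adjusted p = 0.237) and control replicate 2 (0.18, adjusted p = 0.447), and its mean was 0.66 without control replicate 3. Over all alternatives, the interferon list fell short in 5 of 24, with means from 0.07 to 1.64. The complement list did so in 6 of 26, with means from 0.1 to 0.66. Both ranges pool edgeR fold changes with limma differences on the log2(FPKM + 1) scale.

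Lists of tissue that borders the ventricles and the brain surface were lower, with control replicate 3 setting much of the size. All 13 choroid plexus genes were lower, by a mean of -4.51 (adjusted p = 6.79e-04; adjusted p = 0.75 with an estimated correlation), and 7 passed when adjusted over the list alone. Slc4a5, a bicarbonate transporter, had a log2 fold change of -7.45 (SE 2.29) and the water channel Aqp1 of -4.87 (SE 1.60), which were -2.65 and -0.92 without control replicate 3. Without control replicate 3 the choroid plexus mean was -0.46 (adjusted p = 0.0343). All 10 ependymal genes were lower, with a mean of -0.95 (adjusted p = 0.0230; adjusted p = 0.75 with an estimated correlation), led by Cfap126 (-1.56, SE 0.512) and Rsph1 (-1.33, SE 0.483), which build motile cilia. Of 12 meningeal genes, 9 were lower, with a mean of -0.53 (adjusted p = 0.0237; adjusted p = 0.77 with an estimated correlation), among them the collagens Col1a1 (-0.73, SE 0.234) and Col3a1 (-1.45, SE 0.5). The ependymal list was lost without knockdown replicate 1 (adjusted p = 0.263), control replicate 1 (0.231) or control replicate 3 (mean -0.59, adjusted p = 0.300). The meningeal list was lost without knockdown replicate 1 (adjusted p = 0.0982), knockdown replicate 3 (mean -0.27, 0.403), control replicate 2 (0.0757) or control replicate 3 (-0.12, 0.456), while its mean was -0.95 without knockdown replicate 2 and -0.80 without control replicate 1.

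**Figure D3:**
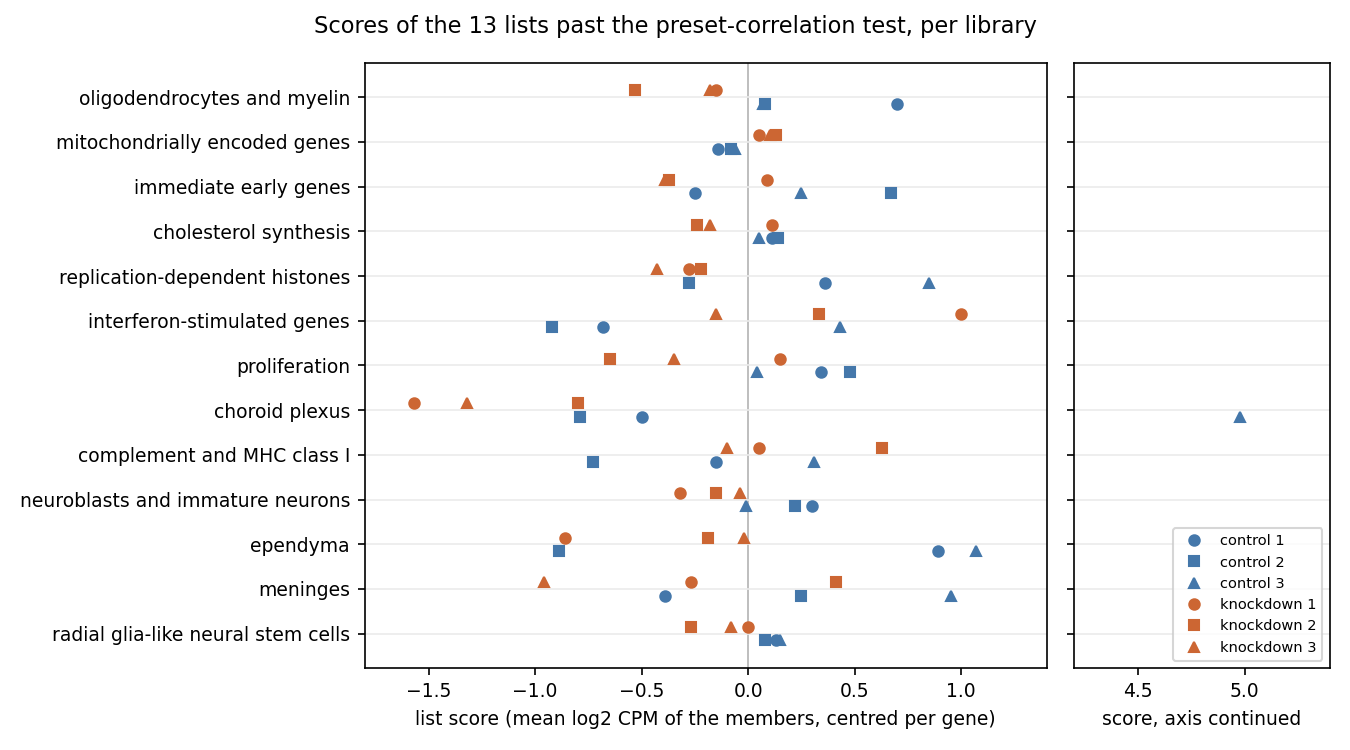
Score of each of the 13 lists in each library, that is, the mean over the list's genes of the log2 CPM after centring each gene over the 6 libraries; blue marks control and orange knockdown libraries, the symbol gives the replicate, and the right panel continues the axis at the same scale. The choroid plexus score of control replicate 3 is 4.98, and the myelin scores of the knockdown libraries, -0.53 to -0.15, lie below those of all 3 controls.

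The lists closest to the target and to the study's question did not pass. The BDNF and TrkB signalling list had 17 of 32 genes higher and 15 lower, with a mean of -0.07, a median of 0.01 and a camera adjusted p of 0.927. Its leading members were Bdnf and Gab1, a docking protein of receptor tyrosine kinases, at -0.46 (SE 0.202), which was -0.21 without control replicate 1. The list mean was -0.03 without control replicate 3. The PRP19 complex list had 10 of 16 lower and a mean of -0.04 (adjusted p = 0.626), led by Cwc15 (-0.12, SE 0.0811) and the cyclophilin Ppil1 (-0.24, SE 0.160). Core spliceosome genes were higher for 19 of 30, with a mean of 0.02 (adjusted p = 0.359), led by Snrpd3 (0.28, SE 0.115) and Prpf6 (0.12, SE 0.0616). SR proteins and hnRNPs were lower for 15 of 24, with a mean of -0.03 (adjusted p = 0.431), led by the splicing factor kinase Clk1 (-0.14, SE 0.0639) and Srsf6 (-0.14, SE 0.0669). These are gene-level totals, and no value here measures splicing.

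The lists for the main neuronal classes did not pass. The camera adjusted p was 0.449 for dentate granule neurons, 0.265 for CA1 pyramidal neurons (mean 0.19), 0.883 for CA2 and CA3 pyramidal neurons, and 0.0580 for GABAergic interneurons, of which 16 of 20 were higher. It was 0.297 for presynaptic genes, 0.927 for postsynaptic glutamatergic genes, and 0.883 for voltage-gated channels. Among glia it was 0.883 for astrocytes, 0.297 for reactive astrocytes, 0.169 for homeostatic microglia, 0.127 for activated microglia, and 0.137 for oligodendrocyte precursors. For endothelium and pericytes it was 0.883, for MHC class II 0.431 (6 of 8 genes lower), for T cells 0.449 (only 4 of 15 listed genes tested), and for blood 0.743. Neighbouring regions gave 0.898 for thalamus and 0.743 for cortex and subiculum. Stress lists gave 0.883 for p53 targets, 0.883 for the DNA damage response, 0.206 for the unfolded protein and integrated stress response, and 0.789 for apoptosis and necroptosis. Alzheimer's disease genes gave 0.431, with 15 of 21 lower, and Wnt and beta-catenin signalling 0.359. Adjusted over their list alone, 6 genes of lists that did not pass were under the threshold: Fibcd1 of the CA1 list (0.83), Fgfr3 of the astrocyte list (0.36), Enpp6 (-1.10) and C1ql1 (-0.66) of the oligodendrocyte precursor list, Trbc2 of the T cell list (-1.55), and Plekhg1 of the thalamus list (-0.39). For Trbc2, at 0.446 FPKM after Cre and 1.36 FPKM in the controls, that adjustment covered only 4 genes, 2 higher and 2 lower.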

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

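Tests marked as added were chosen after seeing the data. The count of genes past the threshold was 0 in edgeR and stayed at 0 with RLE factors, without a count filter, with the replicate block and with counts divided by 4 (added). It was 0 to 2 when each library was left out in turn. Without control replicate 1 the count was 2, Phc3 and Xist, and there Xist follows sex, since the controls left have Y-linked counts. It was 1 with robust dispersions (added), a mean of at least 5 FPKM in edgeR (added) and a sex term (added), and 74 in DESeq2. In limma on log2(FPKM + 1) it was 0, 1 with quantile normalization, 1 with a robust trend, 3 with arrayWeights, 6 with a mean of at least 5 FPKM, and 0 in the other limma fits. Of genes at an unadjusted limma p under 0.05, 417 of 1111 were higher, 300 of 1222 with TPM and 575 of 1052 with median centring, so scaling moved the share of directions. At an unadjusted p under 0.05 and an absolute log2 fold change of at least 1 it was 330, with 162 higher, and 0 when the adjusted p was required too. Why the count differed between these fits was not tested. The Bcas2 log2 fold change was negative and not past the threshold in all 27 alternatives. It ran from -0.122 with TPM to -0.055 without control replicate 1, and from -0.093 to -0.055 when libraries were left out.

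The count of lists was 13, 10 to 14 when libraries were left out, 4 with a mean of at least 5 FPKM in edgeR (added) and also 4 in limma, where 36 lists could be tested, and 0 with an estimated correlation and in fry. Elsewhere it was 9 to 16. The 9 came with the sex term (added) and held 8 of the 13: the choroid plexus (-0.49, adjusted p = 0.541), complement and MHC class I (0.0656) and stem cell (0.0868) lists fell short, and the immediate early and meningeal lists changed sign. The myelin, cholesterol and histone lists passed in every refit at the preset correlation that could test them. Of these, only the myelin scores did not overlap between the groups. For cholesterol, knockdown replicate 1 (0.11) lay above control replicate 3 (0.05). For histones, knockdown replicate 2 (-0.22) lay above control replicate 2 (-0.28). The replicate block left 0 genes and 13 lists, 12 of them shared, and lost the meningeal list (adjusted p = 0.0540); same-numbered libraries had correlations of -0.01, -0.05 and -0.10, so the numbers were not taken to pair the animals. Some signs turned. With the sex term (added), the means were 0.06 for immediate early genes, 0.26 for meninges and -0.03 for the core spliceosome. In the 4 libraries without Y-linked counts (added) they were 0.06, 0.27 and -0.03. Both fits set the knockdown libraries against control replicate 1 alone, so they are a single comparison. The core spliceosome mean, 0.02, was -0.01 without knockdown replicate 2 or control replicate 2, -0.03 with TPM, -0.02 with arrayWeights, and 0.00 at pseudocounts of 0.1 and 0.01, where it was just below 0. mt-Nd1 was at -0.02 with quantile normalization. The cause was not tested. Of 434 values for 17 lists under alternatives, 367 kept direction and side of the threshold, 54 fell short of it, 1 newly passed and 12 changed sign; of 1222 for 48 named genes, 1200 kept both, 21 newly passed and 1 changed sign.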

Other observations

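The tests of GO and KEGG terms, of other splits and of the 4 libraries without Y-linked counts were chosen after the results were seen. So were the permutation and fry tests of lists in part of the libraries. The use of refits without a library to weigh explanations was chosen then too. The refits themselves, DESeq2 and the estimated correlation were planned. Over 1973 GO and KEGG terms, 13 passed camera with the preset correlation, 5 higher and 8 lower after Cre, and 0 passed with an estimated correlation, where each adjusted p was 0.997. Genes of the motile cilium, which ependymal cells carry, were lower along with the ependymal list, whose scores were 0.89 and 1.07 in control replicates 1 and 3 and -0.89 in control replicate 2: 33 of 39 genes of the 9+2 motile cilium term had a negative log2 fold change, with a mean of -0.47 (adjusted p = 0.0283), and 25 of 32 axoneme assembly genes did, with a mean of -0.42 (adjusted p = 0.0310). The GO term of the centromeric (CENP-A containing) nucleosome was lower for all 16 members, with a mean of -0.69 (adjusted p = 0.0176), and 25% of it lay in the fixed lists. The wider nucleosome term had 41 of 56 genes lower, with a mean of -0.38 (adjusted p = 0.0299). How far the members of these terms overlap was not tested. The KEGG term for Hippo signalling in multiple species had 21 of 27 lower, with a mean of -0.18 (adjusted p = 0.0310). Oxidative phosphorylation was higher for 90 of 127 genes, with a mean of 0.07 (adjusted p = 0.0439). The proteasome complex had 47 of 55 genes higher, with a mean of 0.11, and did not pass (adjusted p = 0.0605).

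The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For edgeR the comparison decides nothing, since the real split gave 0 genes and all 10 splits reach a count of 0; the highest other gave 4. In DESeq2 the real split gave 74 genes, 3 splits with the real split included gave as many, and the highest other, with knockdown replicates 1 and 3 and control replicate 2 against the rest, gave 210. The real split gave 13 lists, 2 splits with the real split included gave as many, and the highest other gave 14. For GO and KEGG terms the count was 13, 4 splits with the real split included gave as many, and the highest other gave 33.

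The choroid plexus, ependymal and meningeal lists were lower after Cre. A candidate explanation is choroid plexus tissue carried over in control replicate 3, whose Ttr and Enpp2 reached 4180 and 575 FPKM. Without that library the choroid plexus mean went from -4.51 to -0.46 and the meningeal mean from -0.53 to -0.12, while the ependymal mean, from -0.95 to -0.59, was not decided. An effect of the knockdown on what was left of the choroid plexus difference stays open: its exact permutation p of 0.20 decides nothing, since 3 against 2 libraries give none under 0.10. Of the 13 choroid plexus genes, Enpp2 is also made by oligodendrocytes.

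Immediate early genes were lower after Cre, by a mean of -0.49. A difference in sex between the groups may account for it: in the 4 libraries without Y-linked counts the mean was 0.06. These hold control replicate 1 as their only control, so a property of that animal would give the same value. A high level in control replicate 2 alone was not decided, since the mean without it was -0.23. An effect of the knockdown stays open too, and the exact permutation p of 0.20 decides nothing, since 3 against 3 libraries give none under 0.10.

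Myelin transcripts were lower after Cre, although the synapsin promoter is chosen for neurons. More white matter in control replicate 1 alone accounts poorly for the whole difference, since the mean without that library was -0.34, which is 59% of the mean over all libraries, with an unadjusted p of 0.019 in fry's rotation test, against 0.077 over all 6 libraries. The controls that remain are those with Y-linked counts, so this mean is confounded with sex. Camera's adjusted p without that library, 6.99e-05, holds at the preset correlation, and with an estimated correlation the list did not pass over all 6 libraries (adjusted p = 0.75). The difference in sex stays open, because the mean of -0.96 in the 4 libraries without Y-linked counts rests on control replicate 1. An effect of the knockdown cannot be told apart from a smaller share of white matter in the tissue taken from those animals, and the exact permutation p of 0.10 decides nothing, being the smallest that 3 against 3 libraries allow.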
